A study of Homo sapiens with 12 samples.

How the data were processed

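RNA was measured in 12 libraries of A549 cells, a human lung adenocarcinoma line, carrying a doxycycline-inducible DYRK1B that is either the wild-type kinase (WT) or the Y273F form, in which a tyrosine is replaced by phenylalanine. Per the labels, each line was kept for 7 days with 2 µg/ml doxycycline or without it, with 3 libraries in each of the 4 groups. The series text describes parallel cultures of separate cell populations, and all libraries carry the same batch label. No line without a transgene is among the samples, so an effect of doxycycline itself and an effect of DYRK1B cannot be separated by these comparisons.

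Per the labels' protocols, RNA was isolated on columns and made into QuantSeq FWD V2 libraries, a 3' tag method in which reads start near the polyadenylated end of a transcript and keep its strand. A transgene that lacks the natural 3' end of DYRK1B would therefore give few or no reads assigned to that gene, and the 3' end of the construct is not given in the sources used here. Per the submitters' processing notes, reads were aligned to GRCh38.p14 with STAR. The STAR version, the annotation release and any handling of molecular identifiers are not given in the sources used here. The authors deposited whole-number read counts per gene for each library, without strand, for the transcript strand and for the opposite strand, and a merged count table. All 40605 rows of the merged table are equal in all 12 libraries to a transcript-strand row. The transcript-strand counts were used. Reads assigned to no gene (unmapped, multimapping, ambiguous or outside genes) made up 35.5% to 43.2% of the reads of a library and were left out of library totals and tests. The opposite strand held 7.25% to 8.07% of the counts of both strands.

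Of 60664 gene identifiers, 60463 had an entry in the reference table of names, and 18636 had no official symbol. Coordinates are RefSeq genes on GRCh38.p14. Counts were scaled with TMM factors and to library totals, and are given as CPM. Total counts ranged from 2.82e+06 to 22.3e+06 per library, with a median of 7.67e+06, so that 3 counts correspond to 0.134 to 1.07 CPM. These floors cover counting error only, since reads are not independent molecules where amplification copies are kept.

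Groups were taken from the sample titles. Genes were filtered with filterByExpr (minimum count 10) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in a single model with a mean for each of the 4 groups. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The 4 comparisons were doxycycline against control in each line, the difference of these effects (WT effect minus Y273F effect), and Y273F control against WT control. Log2 fold changes are given with standard errors (SE) or 95% confidence intervals. The comparisons, gene lists, named genes and alternatives were fixed before the data were examined, except where stated. Of 29 gene lists with 800 genes, 26 had at least 5 tested members. These were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, with adjustment over the 26 lists, beside camera with an estimated correlation and the rotation test fry. The level of a list in a library is the mean, over its tested members, of the log2 CPM minus the gene's mean over the 12 libraries.

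The named genes given here are DYRK1B, CDKN1A, CDKN1B, CCND1, LMNB1, MKI67, GDF15, IL6, CXCL8 and DCAF7 in every comparison, then the genes with the highest and lowest log2 fold changes among those past the threshold with a mean of at least 5 CPM and, for comparisons of a pair of groups, no overlap of the groups. None met this part. For each list singled out by camera they are up to 4 members past the threshold or, where fewer than 2 passed, those with the highest mean CPM. Other genes are said to have been chosen after their values were seen. The alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, no filter and a stricter filter on low counts, the DESeq2 Wald test, limma-voom, a term for the replicate number, fits of only the groups compared, unstranded counts, the merged table, leaving out mitochondrial genes and DYRK1B, a test against a 1.5-fold change, a prior count of 0.5 for the lists, and leaving out each library in turn. After the data were seen, fits without 3 libraries that stood apart and with only protein-coding genes were added. The procedure was tested on simulated counts with the means, library sizes and dispersions of the real libraries and 200 changed genes. For doxycycline in the WT line, 66.0% of the genes changed 4-fold and 16.0% of those changed 2-fold were recovered. These shares were 68.0% and 30.0% for doxycycline in the Y273F line, 58.0% and 10.0% for the difference, and 70.0% and 36.0% for the comparison of the lines. In the simulation genes varied independently of each other and every label was right. The shares therefore do not carry over to libraries with variation shared by many genes or with labels in doubt.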

Results

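Gene expression was measured by 3' tag sequencing in 12 libraries of A549 lung adenocarcinoma cells with an inducible DYRK1B gene. DYRK1B is a dual-specificity kinase that phosphorylates itself on a tyrosine of its activation loop while it is being made, and Tyr273 is that residue. The 4 labelled groups of 3 libraries were WT control, WT doxycycline, Y273F control and Y273F doxycycline. Libraries held between 2.82e+06 counts (Y273F doxycycline 1) and 22.3e+06 counts (Y273F control 3). After filtering, 13838 genes were tested.

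DYRK1B (ENSG00000105204, chromosome 19, 39825350 to 39834162), the gene meant to be induced, was read at 28.1 CPM in the library labelled WT doxycycline 1, but at 4.00 and 7.74 CPM in those labelled WT doxycycline 2 and 3. In the WT control libraries it was read at 3.12 to 5.71 CPM. The library labelled Y273F doxycycline 3 had 19.7 CPM and the other libraries of that group 4.58 and 4.82 CPM. The library labelled Y273F control 2 had 12.4 CPM, above 2 of the 3 Y273F doxycycline libraries, while Y273F control 1 and 3 had 2.61 and 3.19 CPM. DYRK1B levels thus did not follow the labels in every library, and all groups compared are groups as labelled, so each comparison holds only as far as the titles match the libraries. DCAF7, a scaffold protein that binds DYRK1B, lay between 213 and 302 CPM in all libraries.

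**Figure D1:**
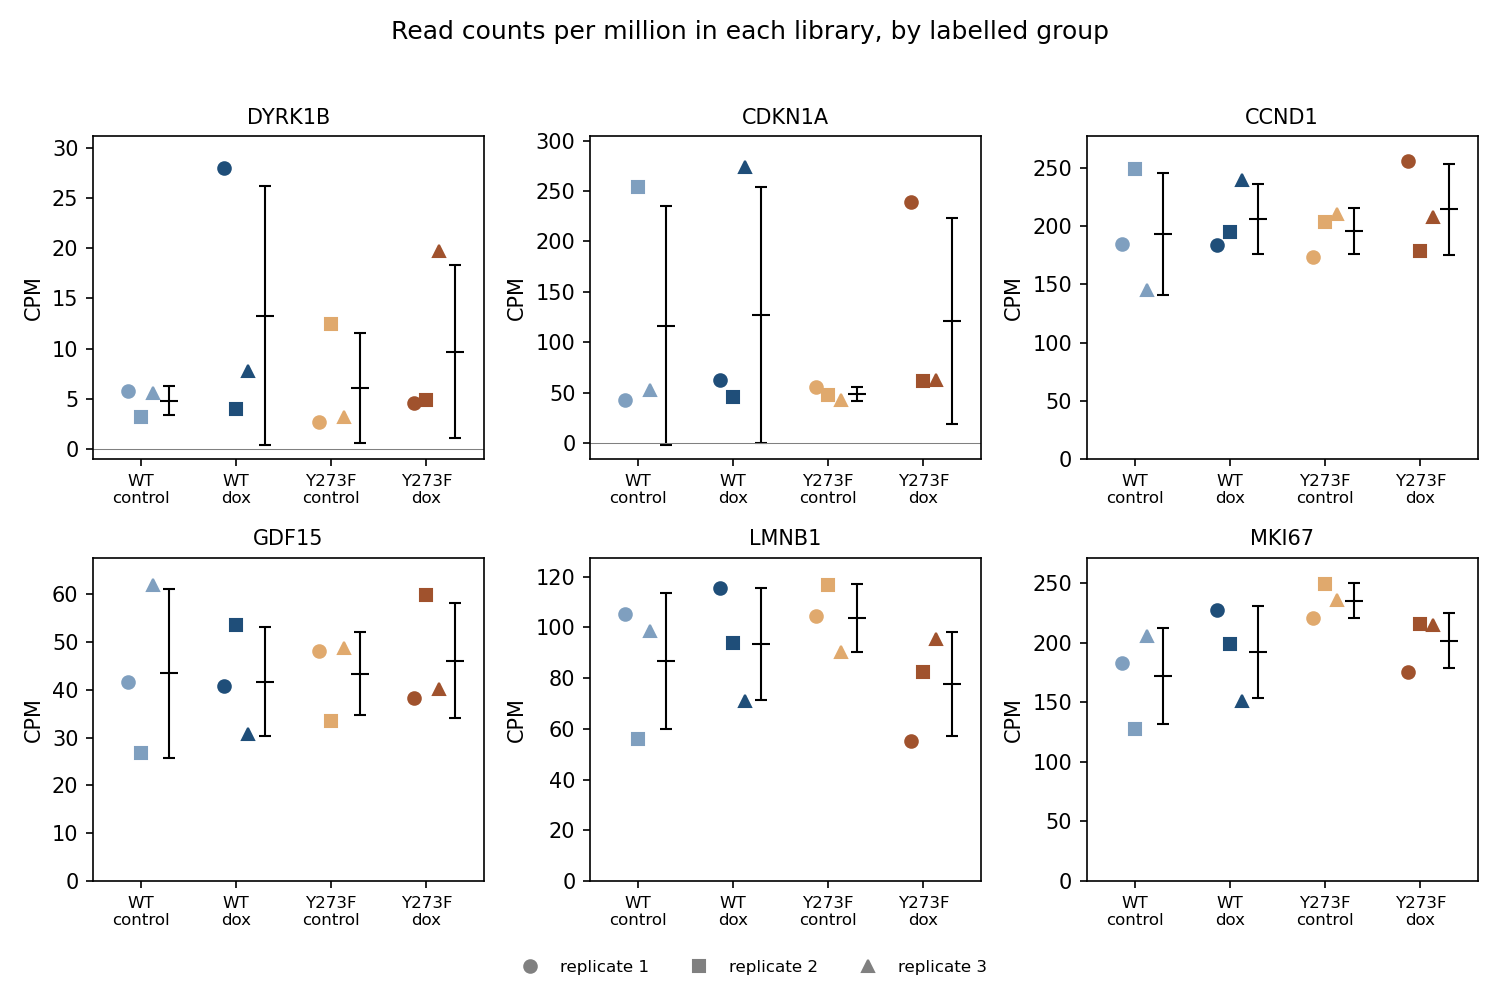
CPM of 6 named genes by labelled group (x axis), with a marker shape for each replicate number and the mean ± SD (n = 3) to the right of each group. CDKN1A was read at 239 to 274 CPM in the libraries labelled WT control 2, WT doxycycline 3 and Y273F doxycycline 1, and at 42.6 to 62.5 CPM in the other 9.

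The libraries labelled WT control 2, WT doxycycline 3 and Y273F doxycycline 1 stood apart from the other 9 on the first principal component, which held 66.3% of the variance of the 500 most variable genes. Their positions were 46.9, 42.7 and 45.2, and the highest of the other 9 was at -4.74. In these 3 libraries CDKN1A, which encodes the CDK inhibitor p21, was read at 254, 274 and 239 CPM, and at 42.6 to 62.5 CPM elsewhere. The matrix protein gene TGFBI had 3389, 2787 and 2458 CPM there against 355 to 674 CPM elsewhere. LMNB1, a nuclear lamina gene, had 56.0, 71.0 and 55.3 CPM there and 82.3 to 117 CPM elsewhere. The proliferation marker MKI67 had 128, 151 and 175 CPM there and 183 to 249 CPM elsewhere. CDKN1B, another CDK inhibitor gene, went the other way from CDKN1A, with 27.1 to 36.1 CPM there and 52.8 to 72.0 CPM elsewhere. The cyclin D1 gene CCND1 was higher there, at 240 to 256 CPM against 145 to 210 CPM. GDF15, a stress-induced secreted factor, overlapped, with 26.8 to 38.4 CPM there and 33.4 to 62.0 CPM elsewhere. KRT18, a simple epithelial keratin chosen after its values were seen, had 8473, 8036 and 6125 CPM there and 2262 to 3362 CPM elsewhere. Another keratin gene, KRT81, overlapped, with 4191 to 4978 CPM there and 4271 to 5677 CPM elsewhere. So did the level of the epithelial junction and keratin list, at 0.09 to 0.36 there and -0.37 to 0.21 elsewhere. The level of the extracellular matrix and mesenchymal list was 1.46, 1.29 and 1.33 there, against at most 0.00 in the other 9. The G1/S E2F target list was at -0.60, -0.66 and -0.59 there and at 0.16 to 0.28 elsewhere, and the p53 target list at 0.57, 0.64 and 0.53 there and at -0.30 to -0.11 elsewhere. These libraries were picked for their position, so no test was run between them and the rest.

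**Figure D2:**
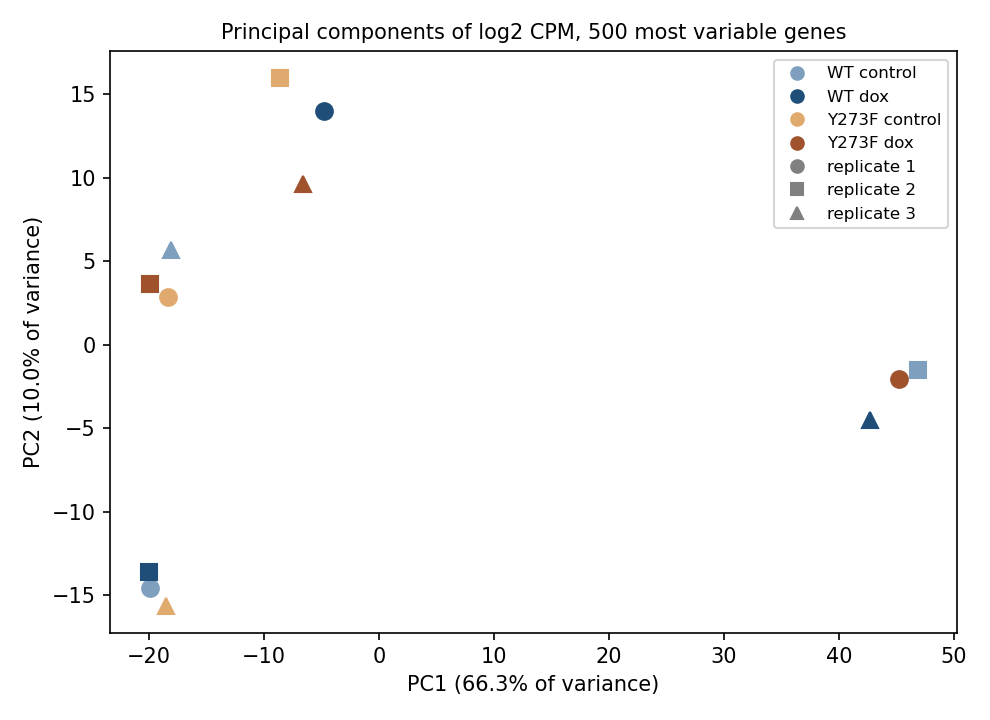
Positions of the 12 libraries on PC1 (x axis, 66.3% of the variance) and PC2 (y axis, 9.99%), from log2 CPM of the 500 most variable genes, coloured by labelled group with a marker shape for each replicate number. The 3 libraries at 42.7 to 46.9 on PC1 carry labels of 3 groups.

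**Figure D3:**
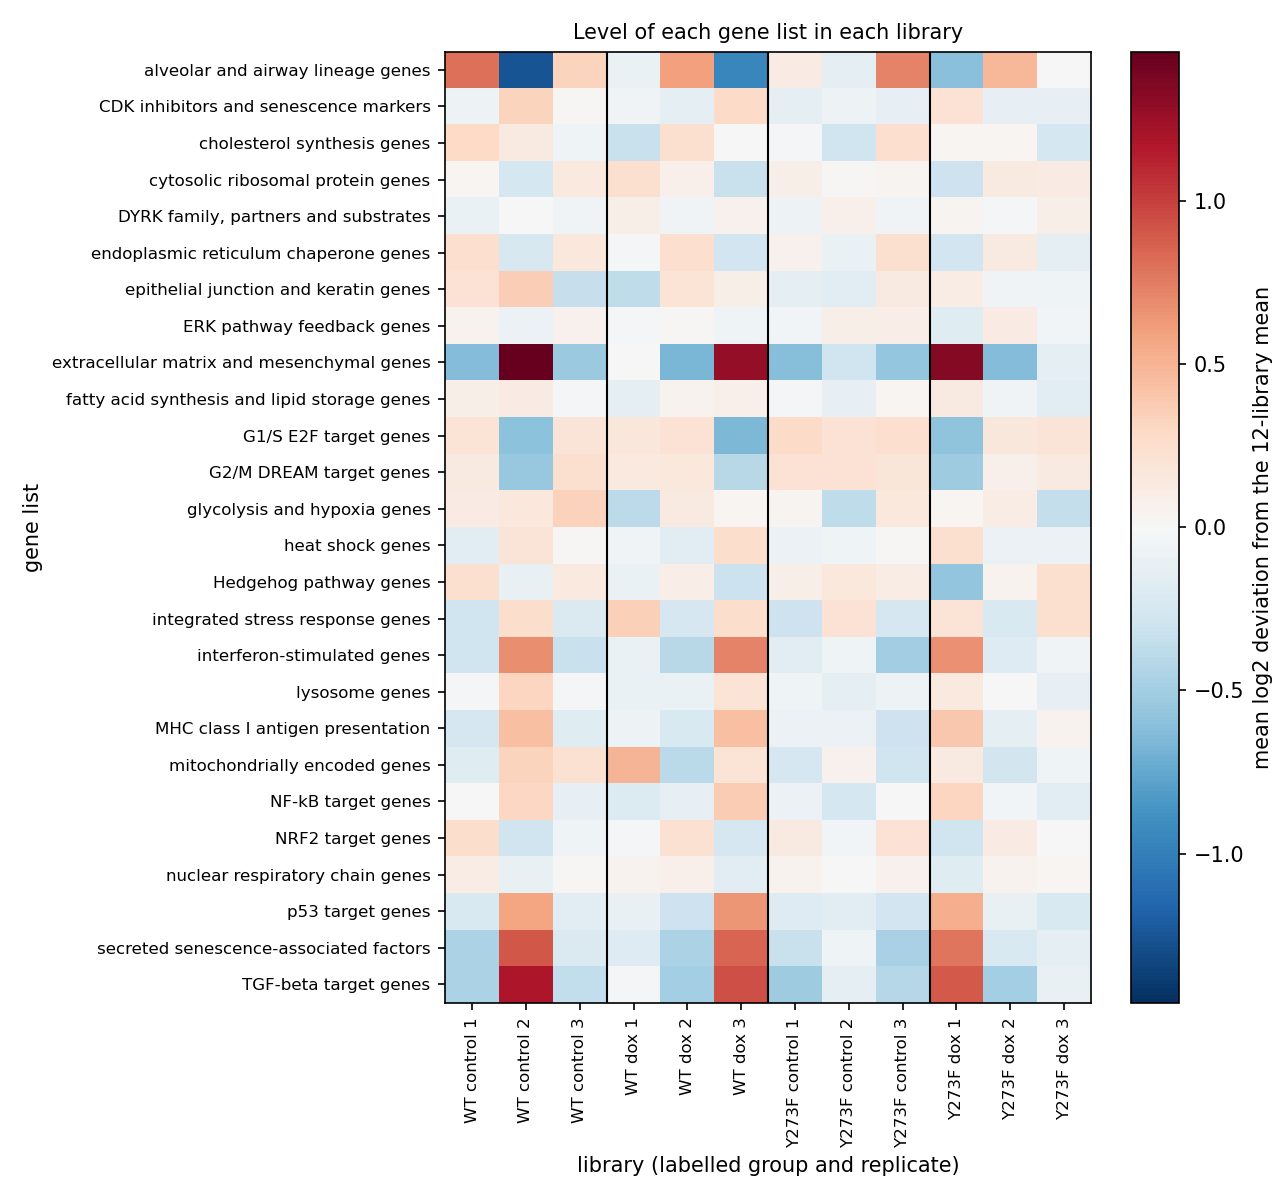
Level of the 26 tested gene lists (rows) in the 12 libraries (columns, by labelled group and replicate), as the mean log2 deviation of the members from their mean over all libraries (colour scale). The extracellular matrix and mesenchymal list was at 1.46, 1.29 and 1.33 in WT control 2, WT doxycycline 3 and Y273F doxycycline 1.

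The comparison of WT doxycycline with WT control asks what 7 days of induced wild-type DYRK1B changed in these cells, and the series title poses this as a question of senescence-like expression. Integrated stress response genes, which restore amino acid supply and translation under stress, rose as a set (28 of 33 tested members with a positive log2 fold change, median 0.18, camera adjusted p = 6.18e-04). Glycolysis and hypoxia genes fell as a set (27 of 30 members negative, median -0.20, adjusted p = 1.16e-04), and so did cholesterol synthesis genes (20 of 24 negative, median -0.11, adjusted p = 0.0253). With an estimated correlation none of the 3 lists passed (adjusted p = 0.970 for each), and with fry the smallest adjusted p was 0.961. The level of the stress response list was 0.35, -0.24 and 0.25 in WT doxycycline 1 to 3 and -0.29, 0.25 and -0.20 in WT control 1 to 3, so the groups overlapped. That of the glycolysis list was -0.38, 0.13 and 0.03 against 0.12, 0.16 and 0.33. Among stress response genes, SLC3A2, a subunit of amino acid transporters, had a log2 fold change of 0.13 (SE 0.36), and its partner SLC7A11, the cystine transporter, 0.17 (SE 0.24). The glycolytic genes GAPDH and ENO1 had log2 fold changes of -0.12 (SE 0.12) and -0.09 (SE 0.10), and the sterol pathway genes FDFT1 and FDPS -0.03 (SE 0.24) and -0.20 (SE 0.17). Without the 3 libraries that stood apart, the median was 0.34 for stress response genes (adjusted p = 5.99e-05), -0.26 for glycolysis genes (adjusted p = 0.00227) and -0.16 for cholesterol synthesis genes (adjusted p = 0.0852), with adjusted p = 0.974 for each with an estimated correlation. That fit had 1 library fewer in each WT group. Among the WT libraries then left, only WT doxycycline 1 had a positive stress response level, and only it had a negative glycolysis level. For both lists the other WT doxycycline library left lay between the WT controls left. The larger medians of these lists therefore do not show a shift shared by the doxycycline libraries. With all libraries the other 23 lists, among them the cell cycle, p53 and secreted factor lists, had adjusted p = 0.311 to 0.941.

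No single gene passed for doxycycline in the WT line with edgeR's quasi-likelihood test, and 134 of 13838 genes had an unadjusted p under 0.05, where 691.9 would be expected by chance. DESeq2 and limma-voom also called 0 genes, with 160 and 158 at an unadjusted p under 0.05. DYRK1B was at 13.3 ± 13.0 CPM (SD, n = 3) with doxycycline and 4.79 ± 1.45 CPM (SD, n = 3) without, a log2 fold change of 1.44 (95% interval -0.36 to 3.23, adjusted p = 0.9997). CDKN1A was at 127 ± 127 and 117 ± 119 CPM (SD, n = 3 each), a log2 fold change of 0.13 (95% interval -1.64 to 1.91). LMNB1 (0.11, SE 0.27), MKI67 (0.16, SE 0.19), CDKN1B, another CDK inhibitor (-0.06, SE 0.34), CCND1, which encodes cyclin D1 (0.10, SE 0.20), GDF15, a stress-induced secreted factor (-0.07, SE 0.31), CXCL8, which encodes interleukin 8 (0.04, SE 0.83), and DCAF7 (0.11, SE 0.14) had log2 fold changes smaller than their SE. IL6 was not tested, with at most 0.669 CPM in a library. Groups did not overlap in 3.27% of genes, where chance gives 10%. A library that stood apart lay on each side of this comparison: 11 lists passed when WT control 2 was left out and 11 when WT doxycycline 3 was, with 6 without WT control 3 and 7 without WT doxycycline 2.

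The same comparison in the Y273F line asks what the mutated kinase changed. Proliferation genes fell as sets: G2/M DREAM target genes (47 of 49 tested members negative, median log2 fold change -0.27, camera adjusted p = 2.16e-09) and G1/S E2F target genes (44 of 47 negative, median -0.26, adjusted p = 6.25e-07). Extracellular matrix and mesenchymal genes rose as a set (35 of 36 positive, median 0.88, adjusted p = 2.88e-05), as did secreted senescence-associated factors (40 of 48 positive, median 0.39, adjusted p = 0.00796), p53 target genes (25 of 30 positive, median 0.36, adjusted p = 0.0118), interferon-stimulated genes (25 of 31, median 0.32, adjusted p = 0.0191), MHC class I antigen presentation genes (14 of 16, median 0.30, adjusted p = 0.0321) and lysosome genes (24 of 32, median 0.13, adjusted p = 0.0441). Nuclear respiratory chain genes (43 of 54 negative, median -0.07, adjusted p = 0.0239), NRF2 target genes (22 of 27 negative, median -0.15, adjusted p = 0.0321) and endoplasmic reticulum chaperone genes (15 of 17 negative, median -0.15, adjusted p = 0.0324) fell. With an estimated correlation none of these 11 lists passed (adjusted p = 0.841 for each), nor did any with fry (smallest adjusted p = 0.883). In the library labelled Y273F doxycycline 1, which stood apart, the matrix list was at 1.33, and it was at -0.63 and -0.14 in Y273F doxycycline 2 and 3, against -0.62, -0.29 and -0.56 in the Y273F controls. The 4 tested fibroblast and smooth muscle markers, too few for a test, had a median of 1.31, with 4 of 4 positive. The G2/M list was at -0.52 in that library, at 0.08 and 0.13 in the others of its group, and at 0.18 to 0.22 in the controls. Without Y273F doxycycline 1, 1 list passed, without Y273F control 3, 3 lists, and without Y273F control 1, 7 lists. Without all 3 libraries that stood apart, G2/M targets still passed (median -0.13, adjusted p = 0.00116) and ribosomal protein genes passed as well (median 0.09, adjusted p = 0.00736), with adjusted p = 0.995 for both with an estimated correlation. The other medians were then 0.14 for matrix genes, 0.11 for secreted factors, 0.11 for interferon-stimulated genes, 0.09 for MHC class I genes, 0.08 for p53 targets, 0.02 for lysosome genes, -0.05 for G1/S targets, -0.07 for NRF2 targets and -0.09 for chaperone genes, and the median turned to 0.02 for nuclear respiratory chain genes.

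By gene, TOP2A and CENPF, which act in chromosome segregation, had log2 fold changes of -0.21 (SE 0.21) and -0.26 (SE 0.18), and the replication genes RRM1 and PCNA -0.37 (SE 0.27) and -0.42 (SE 0.29). The matrix genes TGFBI and VIM, the latter encoding vimentin, had 1.29 (SE 0.95) and 0.36 (SE 0.38). Of the p53 targets, TNFRSF10B, a death receptor gene, had 0.28 (SE 0.23) and CDKN1A 1.30 (95% interval -0.53 to 3.12), with 121 ± 102 CPM against 48.7 ± 6.81 CPM (SD, n = 3 each). The interferon-stimulated gene IFITM2, an antiviral membrane protein, had -0.13 (SE 0.45). B2M, the light chain of MHC class I, had 0.06 (SE 0.18) and IGFBP4, a secreted growth factor binding protein, 0.04 (SE 0.26). The lysosomal membrane gene CD63 had 0.26 (SE 0.21), the ferritin gene FTL -0.30 (SE 0.29), the chaperone gene HSP90B1 -0.32 (SE 0.19) and the complex III gene UQCRB -0.19 (SE 0.15). DYRK1B was at 9.70 ± 8.67 CPM with doxycycline and 6.08 ± 5.51 CPM without, a log2 fold change of 0.87 (95% interval -0.96 to 2.71). LMNB1 (-0.41, SE 0.27), MKI67 (-0.22, SE 0.19), CDKN1B (-0.32, SE 0.34), CCND1 (0.13, SE 0.20), GDF15 (0.08, SE 0.31), CXCL8 (0.08, SE 0.89) and DCAF7 (-0.16, SE 0.14) did not pass either. For doxycycline in the Y273F line edgeR called 0 of 13838 genes, with 225 at an unadjusted p under 0.05 and a smallest adjusted p of 0.992. DESeq2 and limma-voom called 0, with 282 and 223 at an unadjusted p under 0.05. Groups did not overlap in 10.9% of genes (10% by chance). Leaving out a single library brought 1 gene past the threshold in 3 cases, SLX1B without Y273F control 2, RPL32P18 without Y273F doxycycline 2 and FKBP1C without Y273F doxycycline 3, all named after their values were seen and all with near-identical copies in the genome.

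The difference of the doxycycline effects, WT minus Y273F, tests whether the response depended on which kinase was induced. G2/M DREAM targets (46 of 49 positive, median 0.27, camera adjusted p = 2.06e-07) and G1/S E2F targets (43 of 47 positive, median 0.25, adjusted p = 6.09e-04) had a more positive effect in WT as sets. Matrix and mesenchymal genes (34 of 36 negative, median -0.83, adjusted p = 0.00454), glycolysis and hypoxia genes (24 of 30 negative, median -0.16, adjusted p = 0.0121), lysosome genes (23 of 32 negative, median -0.20, adjusted p = 0.0177), secreted factors (42 of 48 negative, median -0.35, adjusted p = 0.0287) and p53 targets (26 of 30 negative, median -0.27, adjusted p = 0.0330) had a more negative effect. With an estimated correlation none passed (adjusted p = 0.783 for each), and with fry the smallest adjusted p was 0.875. The 4 tested fibroblast and smooth muscle markers, too few for a test, had a median of -1.17, with 4 of 4 negative. Without the 3 libraries that stood apart, the median turned to 0.08 for matrix genes and was -0.02 for secreted factors, -6.61e-05 for p53 targets, 0.07 for G1/S and 0.06 for G2/M targets, -0.08 for lysosome genes and -0.17 for glycolysis genes. For the difference edgeR called 0 genes, with 165 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, with 185 and 161. The difference was -1.16 for CDKN1A (95% interval -3.70 to 1.37), 0.56 for DYRK1B (SE 1.16), 0.51 for LMNB1 (SE 0.38) and 0.38 for MKI67 (SE 0.27) on the log2 scale. It was 0.26 for CDKN1B (SE 0.48), -0.03 for CCND1 (SE 0.28), -0.15 for GDF15 (SE 0.43), -0.04 for CXCL8 (SE 1.24) and 0.27 for DCAF7 (SE 0.20). No gene was called in both lines, as none was called in either, and across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.120 and a Spearman correlation of 0.0799. For the difference 0 lists passed without Y273F doxycycline 1, 1 without WT control 2, 2 without WT doxycycline 1, 4 without WT doxycycline 2, 13 without WT control 1 and 15 without WT doxycycline 3. Without Y273F doxycycline 2 or 3, RPL32P18 or FKBP1C passed, as for doxycycline in the Y273F line.

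The lines were also compared without doxycycline, Y273F control against WT control, both at day 7 as labelled. G2/M DREAM targets (45 of 49 positive, median log2 fold change 0.18, camera adjusted p = 4.20e-07), G1/S E2F targets (44 of 47 positive, median 0.26, adjusted p = 1.98e-06) and NRF2 targets (22 of 27 positive, median 0.09, adjusted p = 0.0467) were higher in Y273F control as sets. Mitochondrially encoded genes (13 of 15 negative, median -0.37, adjusted p = 2.12e-04), matrix and mesenchymal genes (33 of 36, median -0.78, adjusted p = 7.64e-04), p53 targets (28 of 30, median -0.31, adjusted p = 0.00416), lysosome genes (26 of 32, median -0.19, adjusted p = 0.00416), glycolysis and hypoxia genes (26 of 30, median -0.16, adjusted p = 0.00438) and secreted factors (38 of 48, median -0.44, adjusted p = 0.0349) were lower. With an estimated correlation none of the 9 passed (adjusted p = 0.653 for each), and with fry the smallest adjusted p was 0.185. The library labelled WT control 2, which stood apart, held the matrix list at 1.46, while WT control 1 and 3 were at -0.63 and -0.54 and the Y273F controls at -0.62 to -0.29. The 4 tested fibroblast and smooth muscle markers, too few for a test, had a median of -1.28, with 4 of 4 negative. Without WT control 2, 2 lists passed, and without WT control 1, 14 lists. Without all 3 libraries that stood apart, the median turned to 0.08 for matrix genes and to 0.08 for secreted factors, and was -0.01 for p53 targets, 0.07 for G1/S and 0.02 for G2/M targets, 0.02 for NRF2 targets and -0.07 for lysosome genes. Glycolysis genes then still passed (median -0.19, adjusted p = 0.0337, or 0.910 with an estimated correlation), and the median of mitochondrially encoded genes was -0.27 (adjusted p = 0.223). Among the control libraries then left, only Y273F control 2 had a negative level of the glycolysis list.

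For the lines without doxycycline, CENPF had a log2 fold change of 0.60 (SE 0.18, unadjusted p = 0.00553, adjusted p = 0.994), TOP2A 0.48 (SE 0.21) and MKI67 0.45 (SE 0.19). The mitochondrial genes MT-RNR2 and MT-ATP6 had -0.24 (SE 0.22) and -0.39 (SE 0.29). CDKN1A was at 48.7 ± 6.81 CPM in Y273F control and 117 ± 119 CPM in WT control (SD, n = 3 each), a log2 fold change of -1.25 (SE 0.83). DYRK1B was at 6.08 ± 5.51 and 4.79 ± 1.45 CPM, a log2 fold change of 0.18 (SE 0.85). LMNB1 (0.25, SE 0.27), CDKN1B (0.06, SE 0.34), CCND1 (0.02, SE 0.20), CXCL8 (-0.57, SE 0.87) and DCAF7 (0.14, SE 0.14) did not exceed their SE, and GDF15 was at 43.4 and 43.5 CPM. For this comparison edgeR called 0 of 13838 genes, with 460 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, with 523 and 478. Groups did not overlap in 10.8% of genes (10% by chance). SLX1B, at most 0.446 CPM in the other 10 libraries and at 63.4 and 66.2 CPM in Y273F control 1 and 3, passed when Y273F control 2 was left out.

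In none of the 4 comparisons did a list member pass when adjusted over the list alone (0 in each). The lists for other cell types had too few tested members for a test: 4 of 12 fibroblast and smooth muscle markers (for doxycycline in the WT line 2 of 4 positive), 2 of 12 leukocyte markers and 0 of 8 endothelial markers. Libraries of the same labelled group were not more alike than others. The mean Pearson correlation of log2 CPM across genes was 0.946 within groups and 0.953 between groups (one-sided permutation p = 0.905, 100000 permutations of the labels), and the library with the highest correlation lay in the same labelled group for 0 of 12 libraries.

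**Figure D4:**
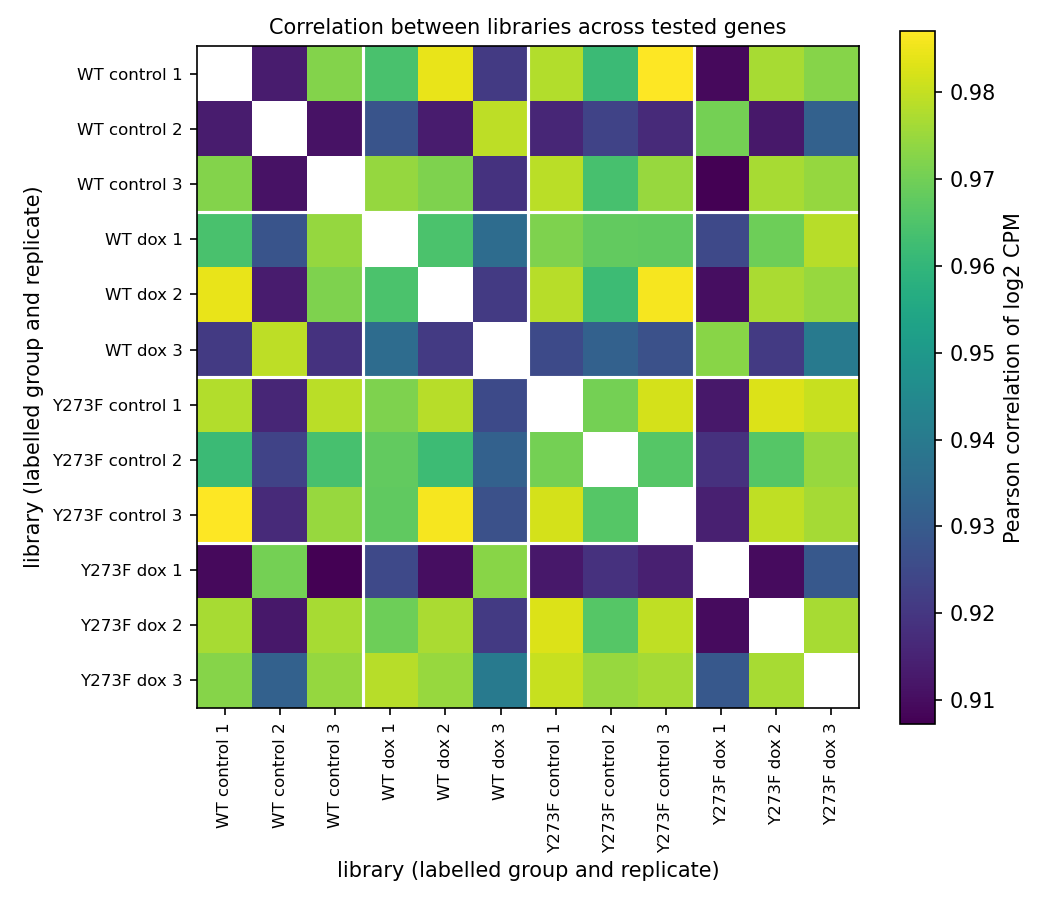
Pearson correlation of log2 CPM across tested genes (colour scale) for each pair of the 12 libraries, ordered on both axes by labelled group and replicate, with white lines between groups and blank cells on the diagonal. For 0 of 12 libraries was the highest correlation inside the own group.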

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

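In this part, the tests of another cell type and of the labelled treatment were chosen after the results were seen, and the thinning test before its result was seen. The effect of doxycycline differed between the lines for 7 gene lists by the camera test of the difference itself (WT effect minus Y273F effect, median log2 difference): secreted senescence-associated factors (-0.35), p53 target genes (-0.27), G1/S E2F target genes (0.25), G2/M DREAM target genes (0.27), extracellular matrix and mesenchymal genes (-0.83), glycolysis and hypoxia genes (-0.16) and lysosome genes (-0.20). With an estimated correlation no list passed (adjusted p = 0.783 for each). Of 100 regroupings of the 12 libraries, the labelled one included, 61 gave at least 7 lists and the highest other gave 18, so chance could not be excluded for this count. On the opposite strand DYRK1B had 1 read in Y273F control 3 and 0 in the other libraries, and that strand held 7.25% to 8.07% of counts with doxycycline and 7.35% to 7.95% without.

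A pattern seen in most of these lists is that the libraries labelled WT control 2, WT doxycycline 3 and Y273F doxycycline 1 stood apart. CDKN1A, CCND1 and matrix genes were high there, and CDKN1B and proliferation genes were low. Depth does not account for this pattern. With every library thinned to 2.82e+06 counts, the lowest of these 3 and the highest of the other 9 were 40.0 apart on the first component. The range among those 9 was 18.3. Fibroblasts or smooth muscle cells in the culture would bring COL1A2, COL3A1 and DCN along with COL1A1, but these 3 genes together came to at most 0.440% of COL1A1 in the libraries that stood apart, although LUM (11.3 to 13.6 CPM against at most 1.54 CPM elsewhere), ACTA2 (34.5 to 36.4 against 11.4 to 23.4 CPM) and MYL9 (11.5 to 21.1 against at most 0.443 CPM) were higher there. Doxycycline as labelled is argued against by values already seen: the 3 libraries carry labels of 3 groups, WT control 2 among them at 46.9 on the first component, and 4 of the 6 doxycycline libraries were at -4.74 or lower. What stays open is whether they are libraries of a shared condition under wrong labels or shared a position during library preparation, both taken up among the other observations, or are cultures that reached this state apart from the treatment, which was not tested.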

How the results depend on the processing

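The alternatives without the 3 libraries that stood apart and with only protein-coding genes were chosen after the data were seen. The count of 0 genes in each comparison, and the overlap of 0, held under every setting except some that left out 1 library: over those, the count ranged from 0 to 1 for doxycycline in the Y273F line (1 without Y273F control 2, Y273F doxycycline 2 or Y273F doxycycline 3), for the difference (1 without Y273F doxycycline 2 or 3) and for the lines without doxycycline (1 without Y273F control 2). The genes were SLX1B, RPL32P18 and FKBP1C, and the cause was not tested. Of 5937 values of the named genes under alternatives, 5500 kept their sign and 437 changed it, with no adjusted p below 0.805 for any. The list counts were 3, 11, 7 and 9 for doxycycline in WT, doxycycline in Y273F, the difference and the lines. They fell to 0, 0, 0 and 0 with an estimated correlation and to 0, 0, 0 and 0 with fry. Among the lists that passed at the preset of 0.01, the estimate ran from 0.140 (glycolysis and hypoxia) to 0.772 (G2/M DREAM targets). The estimate comes from residuals about the labelled group means, so differences between libraries that cross these groups enter it. In the fit without the libraries that stood apart, camera with an estimated correlation still gave adjusted p = 0.910 to 0.995. With a preset below the estimate, camera gives smaller p-values. For fry the cause was not tested. Without the 3 libraries they were 2, 2, 0 and 1, with fewer libraries in the fit. Leaving out 1 library gave 3 to 11 lists for WT (11 without WT control 2 or WT doxycycline 3, 7 without WT doxycycline 2, 6 without WT control 3), 1 to 13 for Y273F (7 without Y273F control 1, 3 without Y273F control 3, 1 without Y273F doxycycline 1), 0 to 15 for the difference (15 without WT doxycycline 3, 13 without WT control 1, 4 without WT doxycycline 2, 2 without WT doxycycline 1, 1 without WT control 2, 0 without Y273F doxycycline 1) and 2 to 14 for the lines (14 without WT control 1, 2 without WT control 2). In residuals from the labelled group means, the 18 same-numbered pairs had correlations of -0.663 to 0.540, 3 of them over 0.1. By these residuals 3 of 12 libraries correlated best with their own number. As the profiles did not follow the labelled groups, this check cannot show whether replicates were paired. With the replicate number as a block, 0 genes were called in each comparison and the overlap was 0, with 81, 116, 85 and 295 at an unadjusted p under 0.05, and 3, 10, 7 and 8 lists passed. Depth limits genes near the floor of 3 counts, such as IL6, which had at most 5 reads in a library.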

Other observations

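The genes in this part, the tests of wrong labels and of library position, and the regroupings for counts of genes and for the overlap were chosen after the values were seen. The libraries that stood apart are numbers 2, 6 and 10 of the sample descriptions, and DYRK1B CPM was highest in numbers 4, 8 and 12. Other gene groups also fell into sets of libraries that cross the labelled groups. The integrated stress response list was at 0.20 to 0.35 in WT control 2, WT doxycycline 1 and 3, Y273F control 2, and Y273F doxycycline 1 and 3, and at -0.30 to -0.20 in the other 6. The libraries with the higher level are numbers 2, 4, 6, 8, 10 and 12. The glycolysis and hypoxia list was at -0.38, -0.37 and -0.35 in WT doxycycline 1, Y273F control 2 and Y273F doxycycline 3, the libraries with the highest DYRK1B CPM, and at 0.03 to 0.33 in the other 9. The cholesterol synthesis list was at -0.33, -0.29 and -0.26 in those libraries and at -0.06 to 0.29 elsewhere. The gel-forming mucin MUC5AC was read at 75.0, 84.3 and 92.0 CPM in WT control 1, WT doxycycline 2 and Y273F control 3, at 21.6 to 43.2 CPM in 6 libraries, and at 0.223, 1.24 and 2.46 CPM in WT control 2, WT doxycycline 3 and Y273F doxycycline 1. In these last 3 libraries the plasma copper protein gene CP was at 7.36, 16.4 and 6.69 CPM, against 73.8 to 312 CPM in the other 9, and the smooth muscle actin-binding gene TAGLN at 136, 120 and 122 CPM, against 1.13 to 10.8 CPM. CDKN2A and CDKN2B, CDK inhibitor genes of a shared locus, had 0 reads in all 12 libraries, which allows up to 0.0308 CPM over the pooled counts.

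The expression profiles did not follow the labelled groups, and 11 of 12 libraries correlated best with one whose number in the sample descriptions, which run from 1 to 12 through the groups, differed by a multiple of 4. Depth is argued against, as after thinning to the smallest total 0 of 12 libraries correlated best with one of their own group. A candidate explanation is that labels were attached to the wrong libraries, for example if titles were filled in group by group over libraries numbered in another order: of 12 genes on in 6 libraries (at least 1 CPM) and at least 4 times lower in the other 6, 6 shared a single split, and 0 followed the labelled lines. These were the cancer-testis antigen genes CSAG1 (8.96 to 14.1 CPM against at most 0.829 CPM) and MAGEA12, with UGT8, EDIL3 and NALF1, on in WT control 3, WT doxycycline 1, Y273F control 1 and 2 and Y273F doxycycline 2 and 3, and the cadherin gene CDH10, on in the others. The libraries with CSAG1 on are numbers 3, 4, 7, 8, 11 and 12, and those with CDH10 on are 1, 2, 5, 6, 9 and 10. Position during library preparation, taken to give graded differences and not described in the sources used here, stays open: 2 genes sharing a split of 6 against 6 differed at least 20-fold, and 6 genes did so between the 3 libraries that stood apart and the other 9, of which 4 (MYL9, TIMP3, KCNQ3 and MUC5B) had at least 10 reads in every library of the higher side, but 5 were asked for to exclude position and this minimum was set after the count of 6 was seen, so the count for the 3 libraries decides nothing.

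Other groupings of the libraries were compared with the labelled ones. For doxycycline in the WT line, doxycycline in the Y273F line and the lines without doxycycline there are 10 splits of 6 libraries, too few for a share under 0.05; the labelled split called 0 genes in each, as large a count as in 10 of 10 splits, and the highest other split called 0, 2 and 2 genes. For gene lists the labelled split gave 3, 11 and 9 lists, 7 of the 10 splits gave as many in each case, and the highest other split gave 17, 15 and 15. For the difference of the effects, all 100 regroupings drawn gave at least the 0 genes of the labelled one, and the highest other gave 2967 genes, which points to a structure of the samples: in that regrouping WT control 2, WT doxycycline 3 and Y273F doxycycline 1 formed a group. No regrouping gave genes shared by both lines, so 100 of 100 equalled the labelled overlap of 0, and the highest other was 0. A count of 0 is equalled by any regrouping, so these comparisons of gene counts and of the overlap say nothing about chance. These values sort the libraries into sets that cross the labelled groups, but do not establish which line or treatment a set had. For that reason no comparison was run under other labels.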
